A study of Danio rerio with 18 samples.

How the data were processed

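Messenger RNA from adult zebrafish ventricles was sequenced in 15 libraries of 5 groups with 3 libraries each. Per the labels, 4 groups carried a transgene that drives a tamoxifen-inducible Gal4 in cardiomyocytes together with either UAS:RFP, a red fluorescent protein, or UAS:GFP-HRAS, the oncogene HRAS fused to green fluorescent protein. These fish received 4 pulses of 2.5 uM 4-hydroxytamoxifen (4-OHT) and either 0.05% DMSO, the vehicle, or 0.5 uM rapamycin, an inhibitor of the kinase TOR, over 16 days. The other group carried the driver alone and was sampled 7 days after cryoinjury (7 dpci), a freezing injury from which the zebrafish heart regenerates, with no drug treatment. The labels list 18 samples. The 3 uninjured samples were not analysed here, so the comparisons that needed them were not run: the injury effect, its difference from the HRAS effect, their overlap and the tests of injury-called genes. Groups came from the sample titles, and columns named UR were read as the UAS:RFP line. The labels do not say whether the libraries of a group came from separate animals or pools. Each p-value of the gene tests therefore measures only the spread between these libraries.

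Per the labels' protocols, RNA was extracted with QIAzol and a micro column kit with DNase, and libraries were made with the CORALL mRNA kit, whose molecules carry unique molecular identifiers (UMIs). Per the submitters' processing notes, the tools were HISAT2 2.1.0, UMI-tools 1.1.1 and featureCounts 1.6.0, with genome build GRCz11; the annotation release and the use of strand in counting are not given in the sources used here. The deposited values are whole-number counts per gene in 2 tables, 1 for the transgenic experiment and 1 for the injury experiment, with 32520 gene identifiers each. The authors deposited these counts without normalization, as the differing column totals show. Genes that overlap on opposite strands and near-identical paralogues may share reads, and their values are uncertain. Symbols came from a table of identifiers and symbols, which gave 29201 of the identifiers a symbol; many are written in human style (MYL7, PCNA), and zebrafish paralogues can then share a symbol. Library totals ran from 15861618 to 20003711 counts.

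Counts were tested in R 4.3.3 with edgeR 4.0.16, using trimmed-mean (TMM) scaling, the default expression filter by group, glmQLFit and glmQLFTest. The 12 transgenic libraries were fitted together, with 16044 genes after the filter, and gave the HRAS effect in DMSO, the HRAS effect in rapamycin, both rapamycin effects and their interaction. The p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05 with no fold threshold. No replicate block entered these fits. Because the uninjured samples were not analysed here, 3 comparisons of the 7 dpci libraries with RFP DMSO, RFP rapamycin and GFP-HRAS DMSO were added after seeing the data, in a fit of all 15 libraries with 16421 genes. They compare groups that differ in table, strain, 4-OHT and vehicle as well as injury, and none of these can be separated from the injury. The design of the transgenic comparisons, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined.

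The log2 fold change is edgeR's estimate with its default prior count, and its standard error was taken as the absolute log2 fold change divided by the square root of F; unshrunk values were looked at before this choice. Levels are CPM, counts scaled to 1 common library size with the TMM factors, given as mean ± SD over 3 libraries, and log2 CPM used a prior count of 2. Where all libraries of a group had 0 counts, the fold is a lower bound against 3 counts over that group. Where the group had 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only. Principal components used the 1000 most variable genes.

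The 32 lists covered DNA replication (S phase), mitosis, sarcomere, calcium handling, fetal and border-zone cardiomyocyte, oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation and TCA cycle, glycolysis, extracellular matrix and fibroblast, epicardium, macrophage and general leukocyte, neutrophil, lymphocyte, endothelium and endocardium, erythrocyte, thrombocyte, smooth muscle, atrium, skeletal muscle, liver, ERK feedback and targets, immediate-early genes, TOR components, amino acid synthesis and ATF4 targets, sterol and fatty acid synthesis, ribosome biogenesis, ribosomal proteins, p53 targets, interferon response, lysosome, and the unfolded protein response with heat shock. Of the listed symbols, 215 matched exactly, 325 after a change of case, 125 through the symbol of the family and 5 through an alias; 30 were not matched and 2 matched more than 3 genes. The lists were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, with adjustment over the lists of each comparison, and again with an estimated correlation. No list passed with the estimated correlation in any of the 8 comparisons. Members were also counted "adjusted over the list alone".

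The named-gene rule took called genes with at least 5 CPM in the higher group, all 3 libraries of 1 group above all 3 of the other and a symbol that is not a clone name, and of these the 10 with the largest change in each direction. It added up to 4 members of each described list with the smallest p, and 16 fixed genes: hrasa, hrasb, nppa, nppb, vmhc, myl7, pcna, mki67, cdk1, dusp6, mpeg1.1, col1a1a, fn1a, cdkn1a, hmgcs1 and asns. The interaction took 5 per direction without the condition on libraries. The symbol vmhc was not matched. hrasa and hrasb were read as both genes with the symbol HRAS, fn1a as both with the symbol FN1, and mpeg1.1 as the 3 with the symbol MPEG1, of which 1 passed the filter in the fit of 12 libraries and 2 in that of 15; identifiers are given where values are. Whether counts of either HRAS gene include reads of the transgene is not given in the sources used here.

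The tests were checked on simulated counts drawn from the real means and library sizes with known changes, on 15564 to 15604 genes per comparison. Of 66 genes changed 4-fold, 77.3% were recovered for the HRAS effect in DMSO, 77.3% for rapamycin in GFP-HRAS, 84.8% for rapamycin in RFP, 78.8% for the HRAS effect in rapamycin and 25.8% for the interaction. Of 67 genes changed 2-fold, the shares in the same order were 11.9%, 10.4%, 4.48%, 4.48% and 1.49%. Alternatives were RLE size factors, library totals alone, no expression filter, the replicate number as a block, DESeq2 1.42.0, only the 6 libraries of both groups, an estimated inter-gene correlation, a 2-fold threshold for overlaps, and each library left out in turn. No pair of libraries held identical counts, and replicates differed by more than sampling noise (lowest chi-square per gene 17.7). Values are given for only some of the genes the rule named, and the result of 1 gene is not reported here.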

Results

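RNA was profiled in ventricles of adult zebrafish in 5 groups of 3 libraries each: UAS:RFP with DMSO, UAS:RFP with rapamycin, UAS:GFP-HRAS with DMSO, UAS:GFP-HRAS with rapamycin, and hearts 7 days after cryoinjury. They are called RFP DMSO, RFP rapamycin, GFP-HRAS DMSO, GFP-HRAS rapamycin and 7 dpci. The title of the series sets cardiac neoplasia driven by an oncogene beside heart regeneration, and the comparisons below ask what HRAS changed in the heart, what a TOR inhibitor changed in both lines, and how the HRAS hearts compared with injured hearts. Library totals were 17028148 to 18945526 counts in RFP DMSO and 16881222 to 19379553 in RFP rapamycin. They were 18173083 to 18566355 in GFP-HRAS DMSO, 15861618 to 19695947 in GFP-HRAS rapamycin and 18105533 to 20003711 in 7 dpci. GFP-HRAS DMSO libraries detected 21265 to 21773 genes, and the RFP DMSO libraries 19903 to 20015. Mitochondrially encoded genes took 16.0% ± 4.95 of counts in RFP DMSO, 13.9% ± 5.83 in RFP rapamycin, 12.6% ± 3.05 in GFP-HRAS DMSO, 16.4% ± 3.04 in GFP-HRAS rapamycin and 18.7% ± 2.37 in 7 dpci (SD, n = 3). The first principal component held 64.7% of the variance, with RFP libraries of both media at -48.7 to -60.6, GFP-HRAS DMSO at 51.7 to 71.2 and 7 dpci at 23.2 to 28.5. GFP-HRAS rapamycin libraries lay at 44.5, 32.8 and -11.9, the last being replicate 3, which stood apart from its group.

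**Figure D1:**
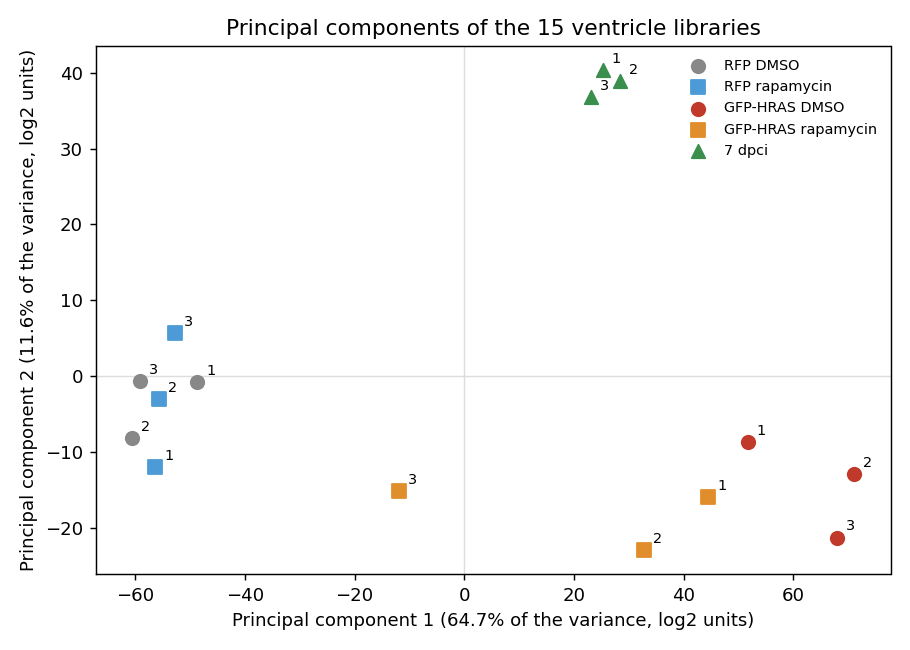
Principal components 1 and 2 of the 1000 most variable genes (log2 CPM), with 1 point per library and colours for the 5 groups. GFP-HRAS DMSO libraries lie at 51.7 to 71.2 on component 1, and GFP-HRAS rapamycin replicate 3, at -11.9, lies between its group and the RFP libraries.

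The HRAS effect in DMSO asks what the oncogene changed in hearts given the vehicle. Of the HRAS genes in the annotation, ENSDARG00000098497 rose from 1.62 ± 0.322 to 7.41 ± 1.09 CPM (SD, n = 3; log2 fold change 2.18 ± 0.38 SE, edgeR with Benjamini-Hochberg adjusted p = 0.00123). The second HRAS gene, ENSDARG00000005651, fell from 17.6 ± 2.6 to 5.95 ± 2.5 CPM (log2 fold change -1.56 ± 0.3, adjusted p = 0.00196). The proliferation marker mki67 rose from 2.0 ± 0.246 to 60.3 ± 15.1 CPM (4.91 ± 0.484, adjusted p = 0.000131). The gene nppb, which encodes a natriuretic peptide of strained myocardium, rose from 226 ± 138 to 1842 ± 978 CPM (3.03 ± 0.714, adjusted p = 0.0056). The cell cycle inhibitor cdkn1a also rose, from 5.19 ± 0.456 to 29.6 ± 1.34 CPM (2.51 ± 0.243, adjusted p = 0.000131). MYL7, a myosin light chain of cardiomyocytes, fell from 9354 ± 291 to 4833 ± 1320 CPM (-0.95 ± 0.288, adjusted p = 0.0186), a call that was lost with library totals (adjusted p = 0.0952) and without GFP-HRAS DMSO replicate 2 (0.062) or 3 (0.0789). For nppa the log2 fold change was 0.41 ± 0.32 (adjusted p = 0.312) and for DUSP6, a phosphatase induced by ERK, 1.49 ± 0.70 (adjusted p = 0.1), which passed with library totals (0.0435) and without GFP-HRAS DMSO replicate 1 (0.0128).

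Over all genes, edgeR called 7621 of 16044 (3991 higher and 3630 lower in GFP-HRAS DMSO), of which 5596 changed at least 2-fold. Without TMM factors the split was 6084 to 1812, as the median of all genes shifted by 0.485 on the log2 scale, so the changes given here are relative to that median. In 10002 genes, 62.3% of those tested, all libraries of 1 group lay above all of the other, where chance gives 10%.

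The largest rises came from groups of genes with near-absent counts in RFP DMSO. Transcripts of mhc2dab, a class II antigen-presenting molecule, reached 291 ± 59.3 CPM against 0.0434 (ratio 7233, counting interval 2002 to 59730), and prf1.8, a perforin of cytotoxic cells, 188 ± 184 CPM against 0.321 (log2 fold change 9.17 ± 1.90, adjusted p = 0.00293). MARCKS (ENSDARG00000008803), an actin-binding protein, was at least 452.6-fold higher at 26.7 ± 8.91 CPM, MYH11 (ENSDARG00000100972), a smooth muscle myosin, at least 259.6-fold and the transcription factor NPAS4 at least 93.6-fold. The ratio was 1676 (300.6 to 66240) for jac2, 640.1 (114.6 to 25310) for the secreted matrix protein spp1, 548.3 (151.5 to 4532) for dicp3.3, 504.2 (90.21 to 19940) for the transcription factor SALL1 ENSDARG00000075891 and 433.8 (119.8 to 3586) for the glucose transporter slc2a3a. SALL1 ENSDARG00000074319, named after its values were seen, fell (-2.30 ± 0.496, adjusted p = 0.00363). Among the largest falls were igfbp1b, which binds insulin-like growth factors, from 177 ± 81.1 to 2.43 ± 3.69 CPM (-6.20 ± 1.49, adjusted p = 0.00605), and HCN4, a pacemaker channel, from 60.7 ± 33.5 to 1.48 CPM (-5.37 ± 0.796, adjusted p = 0.000591). The others were PPP1R3G (-6.45), SLC13A4 (-5.72), the sulfotransferase sult2st2 (-5.66), CYP24A1 (-5.50), COLEC10 (-5.44), ahsg1 (-5.42), MGAT5B (-5.41) and KLHL38 (-5.11), with adjusted p from 0.000131 to 0.012.

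Cell cycle and matrix lists lay higher with HRAS. All 29 measured mitosis genes rose (median log2 fold change 4.93), among them the cyclin CCNA2 (7.05 ± 0.569, adjusted p = 6.89e-05), the spindle protein PRC1 (ENSDARG00000005993, 6.32 ± 0.55), the checkpoint kinase bub1 (5.50 ± 0.444) and UBE2C (5.34 ± 0.444). CDK1, the mitotic kinase, had a ratio of 16.81 (4.406 to 142.8) on 2 counts in RFP DMSO. The list passed in camera at adjusted p = 8.41e-27, and had adjusted p = 0.405 with an estimated correlation. Of 27 S-phase genes 24 rose, and 24 adjusted over the list alone (median 2.33, adjusted p = 1.91e-11, and adjusted p = 0.548 with an estimated correlation). They included the nucleotide synthesis enzymes TYMS (6.70 ± 0.669) and RRM2 (ENSDARG00000020711, 7.11 ± 0.868), the helicase subunit MCM6 (5.05 ± 0.665) and PCNA (1.56 ± 0.248, 135 ± 11.1 CPM against 45.9 ± 4.21). Of 32 matrix and fibroblast genes 26 rose and 3 fell, with the same counts adjusted over the list alone (median 3.03, adjusted p = 8.08e-07, and adjusted p = 0.581 with an estimated correlation). Collagens COL12A1 (ENSDARG00000019601, 6.31 ± 0.874), COL1A1 (3.50 ± 0.52), col1a1a (3.53 ± 0.577) and COL5A2 (2.39 ± 0.331) and the matrix protein SPARC (3.31 ± 0.444) rose. Of the fibronectin genes, FN1 ENSDARG00000019815 rose (5.55 ± 0.874, adjusted p = 0.000772) and FN1 ENSDARG00000006526 had 0.42 ± 0.355 (adjusted p = 0.342). In the smooth muscle list 7 of 11 genes rose, and 7 adjusted over the list alone (median 2.33, adjusted p = 0.0174, lost with library totals at 0.0571, and adjusted p = 0.603 with an estimated correlation). Examples were CNN1 at 4.62 ± 0.848 and CSPG4 at 4.41 ± 0.821. The unfolded protein and heat shock list had 15 of 23 higher and 0 lower, and 17 higher and 1 lower adjusted over the list alone (median 1.17, adjusted p = 0.000188, and adjusted p = 0.581 with an estimated correlation). Among them were the collagen chaperone SERPINH1 (ENSDARG00000075954) at 4.04 ± 0.636 and hsp90aa1.1 at 3.15 ± 0.497.

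Macrophage, lymphocyte and interferon lists lay higher too. Of 23 macrophage and general leukocyte genes 20 rose and 0 fell, and 20 rose adjusted over the list alone (median 3.06, adjusted p = 3.45e-11, and adjusted p = 0.548 with an estimated correlation). The class II invariant chains cd74a (5.03 ± 0.527) and cd74b (5.0 ± 0.457), the leukocyte phosphatase ptprc (3.06 ± 0.301) and the chemokine receptor cxcr3.2 (4.81 ± 0.545) rose, while the macrophage pore protein MPEG1 ENSDARG00000043093, the 1 MPEG1 gene of 3 that passed the filter here, had -0.70 ± 0.802 (adjusted p = 0.49). Of 10 lymphocyte genes 6 rose and 1 fell, and 7 and 1 adjusted over the list alone (median 4.04, adjusted p = 0.0268, lost with library totals at 0.0878, and adjusted p = 0.581 with an estimated correlation). The T cell kinase ZAP70 (6.11 ± 0.807), the cytokine receptor il7r (4.32 ± 0.584) and the immunoglobulin chain ighm (5.15 ± 0.933) rose, and GATA3 fell (-1.52 ± 0.271). Interferon response genes had 12 of 20 higher and 0 lower, and 13 higher adjusted over the list alone (median 1.61, adjusted p = 0.000558, and adjusted p = 0.581 with an estimated correlation). Members included mxb at 4.40 ± 0.587, isg15 at 3.05 ± 0.426 and the immunoproteasome subunits PSMB9 at 3.59 ± 0.46 and PSMB8 at 3.48 ± 0.44. Without GFP-HRAS DMSO replicate 1 the median of the interferon list was 0.907.

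Lists of the endothelium, respiration and translation lay lower. Of 23 endothelial genes 14 fell and 4 rose, and 15 and 4 adjusted over the list alone (median -1.34, adjusted p = 0.000142, and adjusted p = 0.405 with an estimated correlation). Examples were the receptor kdrl at -1.97 ± 0.204, the cadherin cdh5 at -1.70 ± 0.184, NOTCH1 (ENSDARG00000052094) at -1.45 ± 0.176 and the transcription factor ERG at -1.37 ± 0.143. Of 48 ribosomal protein and elongation factor genes 41 fell and 0 rose, and 42 fell adjusted over the list alone (median -0.69, adjusted p = 1.48e-08, and adjusted p = 0.603 with an estimated correlation), such as RPL13A (-1.16 ± 0.198). Nuclear oxidative phosphorylation genes had 12 of 29 lower and 3 higher, and 12 and 3 adjusted over the list alone (median -0.60, adjusted p = 0.00184, and adjusted p = 0.632 with an estimated correlation). Among them were the cytochrome oxidase subunit cox7a1 at -2.98 ± 0.478 and NDUFV2 at -1.57 ± 0.21. Fatty acid oxidation and TCA cycle genes had 12 of 29 lower and 0 higher, and the same adjusted over the list alone (median -0.62, adjusted p = 0.00744, 0.0709 without RFP DMSO replicate 1, and adjusted p = 0.632 with an estimated correlation). Members included MDH2 at -1.98 ± 0.313 and IDH2 at -1.58 ± 0.265. Of 9 erythrocyte genes 7 fell, and 7 adjusted over the list alone (median -1.61, adjusted p = 0.00171, and adjusted p = 0.581 with an estimated correlation). An example was the globin hbaa1 at -1.61 ± 0.316.

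The other lists did not pass. Among cardiomyocyte lists, 10 of 28 sarcomere genes fell and 4 rose (adjusted p = 0.0822; median -0.40, which turned to 0.05 with library totals), with the actin actc1a at -1.24 ± 0.16 and LMOD2 at -1.98 ± 0.272 below 0. Calcium handling had 2 of 12 higher and 3 lower (adjusted p = 0.382). The fetal and border-zone list had 6 of 21 higher and 7 lower (adjusted p = 0.805), with a positive median (0.13) and mean (0.46) and a test pointing down; TAGLN (ENSDARG00000045408) rose by 8.21 ± 1.18 and gata4 had -2.14 ± 0.26. The remaining adjusted p were 0.0601 for mitochondrially encoded genes, 0.757 for glycolysis, 0.805 for epicardium, 0.163 for neutrophil and 0.862 for thrombocyte genes. They were 0.0918 for atrium, 0.505 for skeletal muscle, 0.948 for liver, 0.0849 for ERK feedback and 0.0601 for immediate-early genes, and 0.0918 for TOR components, 0.209 for amino acid synthesis, 0.207 for sterol synthesis, 0.487 for ribosome biogenesis, 0.508 for p53 targets and 0.826 for lysosome. Signs of median, mean and test differed for the thrombocyte (-0.03, 0.13, down), skeletal muscle (1.02, -0.18, down), liver (1.71, -0.42, up) and lysosome (-0.13, 0.04, down) lists. Single members still changed, such as PHGDH, the first enzyme of serine synthesis (6.48 ± 0.939), the ERK target ETV4 (3.25 ± 0.677) and the epicardial podxl (-1.93 ± 0.163). ASNS had 0.61 ± 0.202 (adjusted p = 0.0284), lost without the filter (0.0599) and without RFP DMSO replicate 1 (0.0508), 2 (0.0894) or 3 (0.0834) or GFP-HRAS DMSO replicate 2 (0.0793) or 3 (0.0681), and HMGCS1 1.12 ± 0.302 (0.0109), lost without RFP DMSO replicate 3 (0.0503).

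**Figure D2:**
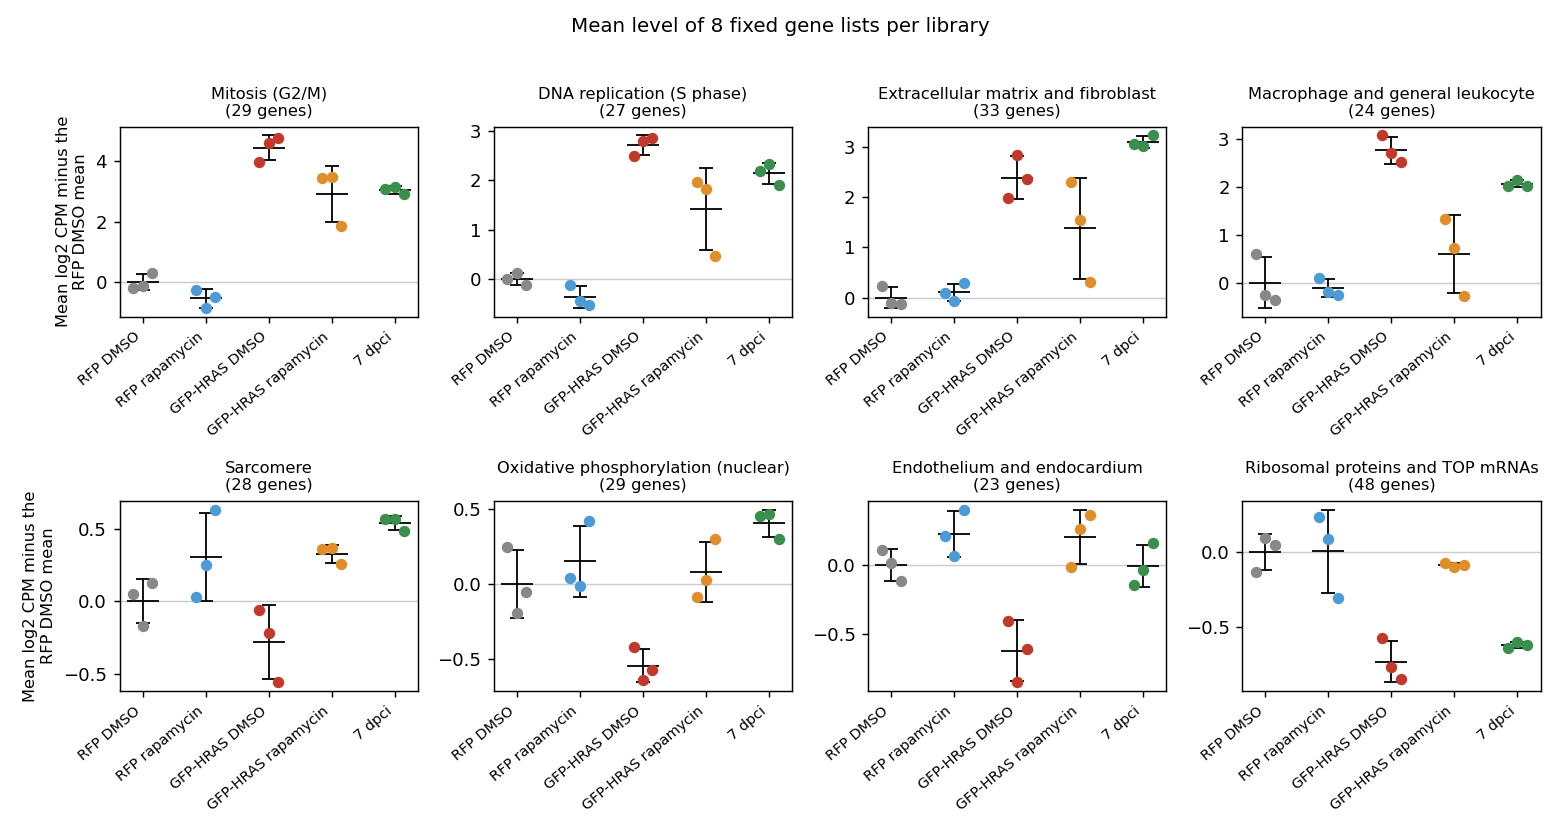
Mean log2 CPM of 8 gene lists per library minus the RFP DMSO mean, with 1 point per library and bars at the group mean ± SD (n = 3) for the 5 groups. Mitosis, S phase, matrix and macrophage lists lie above 0 in GFP-HRAS DMSO, where the median log2 fold changes were 4.93, 2.33, 3.03 and 3.06.

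Rapamycin in GFP-HRAS hearts asks what the TOR inhibitor changed in the GFP-HRAS line. The class II invariant chain cd74a fell from 2807 ± 690 to 185 ± 85.6 CPM (SD, n = 3; log2 fold change -3.93 ± 0.50, edgeR with Benjamini-Hochberg adjusted p = 0.00351). Log2 fold changes were -3.68 ± 0.428 for cd74b (0.00324) and -4.27 ± 0.443 for the T cell receptor chain trbc1 (0.0026). The hedgehog ligand IHH rose from 13.1 ± 7.64 to 162 ± 56.2 CPM (3.63 ± 0.433, adjusted p = 0.00351), and the matrix protein EFEMP1 from 0.793 to 14.1 ± 7.5 CPM (4.14 ± 0.735, adjusted p = 0.00918). The cardiac actin actc1a (1.08 ± 0.159, adjusted p = 0.00559) and the actin regulator LMOD2 (1.39 ± 0.267, adjusted p = 0.0118) rose. The proliferation marker mki67 fell from 60.3 ± 15.1 to 19.6 ± 9.22 CPM (-1.62 ± 0.41, adjusted p = 0.0289). That call was lost without GFP-HRAS DMSO replicate 2 (0.0899) or 3 (0.0832) or GFP-HRAS rapamycin replicate 2 (0.057) or 3 (0.0614) and in a fit of the 6 libraries alone (0.0664). MYL7 rose to 10800 ± 3660 CPM (1.16 ± 0.29, adjusted p = 0.0275), lost with library totals (0.053) and without GFP-HRAS DMSO replicate 2 (0.103) or 3 (0.102) or GFP-HRAS rapamycin replicate 2 (0.0525) or 3 (0.0892). PCNA fell (-1.04 ± 0.245, adjusted p = 0.0226), lost without GFP-HRAS DMSO replicate 2 (0.0693) or 3 (0.0606) or GFP-HRAS rapamycin replicate 3 (0.0561). HRAS ENSDARG00000098497 had -0.17 (adjusted p = 0.787), nppb 0.48 (0.669), nppa 0.26, cdkn1a -0.30 (0.402), col1a1a -0.98 (0.227), FN1 ENSDARG00000019815 -1.91 (0.102), DUSP6 -1.55 (0.165), CDK1 -0.37 (0.724), HMGCS1 -0.28 (0.569), ASNS -0.24 (0.456) and MPEG1 ENSDARG00000043093 -1.22 (0.347).

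edgeR called 1947 genes (936 higher, 1011 lower), and 254 higher and 3218 lower without TMM factors, where the median gene shifted by -0.437. In 34.5% of genes the libraries did not overlap, where chance gives 10%. The count was 533 without GFP-HRAS DMSO replicate 2, 872 without replicate 3, 692 without GFP-HRAS rapamycin replicate 2 and 866 without replicate 3. Among the largest falls were ifi44a8 (-4.82 ± 0.753, adjusted p = 0.00633), plaat1l (-4.42 ± 0.572), ifi44a6 (-4.37 ± 0.797), the interferon-induced GTPase mxc (-4.36 ± 0.769), the chemokine cxcl11.4 (-4.26 ± 0.709) and ZAP70 (-4.21 ± 0.701, adjusted p = 0.0074). Rises included the transcription factor zbtb16b (4.32 to 25.4 CPM, 2.56 ± 0.392, adjusted p = 0.00597). The pacemaker channel HCN4 rose (3.76 ± 0.751, adjusted p = 0.0132; 0.0585 without GFP-HRAS DMSO replicate 2). MYH11 (ENSDARG00000100972) fell (-6.14 ± 1.19, adjusted p = 0.0157; 0.0573 without GFP-HRAS rapamycin replicate 2 and 0.0526 without 3). The call of mhc2dab (-4.29 ± 1.26, adjusted p = 0.0475) was lost without each of the 6 libraries in turn (0.0731 to 0.107) and in DESeq2 (0.0777).

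Macrophage, lymphocyte, interferon, cell cycle and matrix lists lay lower with rapamycin. Of 23 macrophage and leukocyte genes 15 fell and 0 rose, and 19 fell adjusted over the list alone (median -2.1, adjusted p = 7.45e-19, and adjusted p = 0.168 with an estimated correlation). Among them were ptprc at -2.54 ± 0.294 and laptm5 at -2.50 ± 0.366. Of the lymphocyte genes 4 fell, and 4 adjusted over the list alone (median -1.92, adjusted p = 0.00222, and adjusted p = 0.403 with an estimated correlation). Interferon response genes had 4 lower, and 8 lower and 1 higher adjusted over the list alone (median -0.74, adjusted p = 0.00147, 0.0899 and a median of -0.487 without GFP-HRAS DMSO replicate 1, 0.0863 without GFP-HRAS rapamycin replicate 1, and adjusted p = 0.608 with an estimated correlation). Examples were PSMB9 at -2.42 ± 0.431 and isg15 at -1.98 ± 0.404. Of 29 mitosis genes 14 fell, and 22 adjusted over the list alone (median -1.58, adjusted p = 8.7e-12, and adjusted p = 0.403 with an estimated correlation). Of 27 S-phase genes 8 fell, and 18 adjusted over the list alone (median -1.04, adjusted p = 4.94e-09, and adjusted p = 0.403 with an estimated correlation). In the matrix list 1 gene fell, and 0 adjusted over the list alone (median -0.88, adjusted p = 0.000937, and adjusted p = 0.624 with an estimated correlation). Without GFP-HRAS rapamycin replicate 3, the library that stood apart, medians were -0.554 for matrix (adjusted p = 0.0496), -0.648 for S phase and -1.35 for interferon genes. The matrix median was -1.39 without GFP-HRAS rapamycin replicate 1, and the lymphocyte median -1.17 without GFP-HRAS DMSO replicate 1.

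Ribosomal, respiratory, muscle and endothelial lists lay higher. Of 48 ribosomal protein genes 31 rose, and 42 adjusted over the list alone (median 0.64, adjusted p = 1.48e-15, and adjusted p = 0.403 with an estimated correlation). Among them was the elongation factor eef1a1l1 at 1.1 ± 0.173; with library totals the calls of RPL3 (0.93 ± 0.175) and EEF1B2 were lost (0.105 and 0.0874). Oxidative phosphorylation had 11 of 29 higher, and 21 adjusted over the list alone (median 0.67, adjusted p = 5.32e-08, and adjusted p = 0.443 with an estimated correlation). Fatty acid oxidation and TCA cycle genes had 6 of 29 higher, and 10 adjusted over the list alone (median 0.75, adjusted p = 5.06e-06, and adjusted p = 0.528 with an estimated correlation). Sarcomere genes had 12 of 28 higher and 1 lower, and 15 and 1 adjusted over the list alone (median 0.71, adjusted p = 2.01e-06, and adjusted p = 0.403 with an estimated correlation). The fetal and border-zone list had 5 of 21 higher, and 9 adjusted over the list alone (median 0.53, adjusted p = 8.3e-05, and adjusted p = 0.0682 with an estimated correlation). Members included the LIM protein FHL2 (ENSDARG00000042018) at 2.09 ± 0.251. Endothelial genes had 12 of 23 higher, and 16 adjusted over the list alone (median 0.93, adjusted p = 3.92e-08, and adjusted p = 0.0682 with an estimated correlation). An example was the endocardial factor NFATC1 at 1.29 ± 0.225. Mitochondrially encoded genes had 0 called and a median of 0.80 (adjusted p = 0.00124, and adjusted p = 0.624 with an estimated correlation).

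Calcium handling, immediate-early and glycolysis lists had medians above 0, for glycolysis not with library totals. Calcium handling had 3 higher and 1 lower, and 5 and 1 adjusted over the list alone (median 0.61, adjusted p = 0.0225, and adjusted p = 0.403 with an estimated correlation); it was lost without GFP-HRAS DMSO replicate 3 (0.0701) or GFP-HRAS rapamycin replicate 1 (0.0601). Immediate-early genes had 2 higher, and 2 adjusted over the list alone (median 0.67, adjusted p = 0.0117, and adjusted p = 0.683 with an estimated correlation), lost without GFP-HRAS rapamycin replicate 1 (0.0601) or 2 (0.147). Their median was 0.365 without GFP-HRAS rapamycin replicate 2, 1.18 without GFP-HRAS DMSO replicate 1 and 1.02 without GFP-HRAS rapamycin replicate 3. Glycolysis had 3 higher, and 1 adjusted over the list alone (median 0.33, which turned to -0.13 with library totals; adjusted p = 0.0232, and adjusted p = 0.624 with an estimated correlation), lost without GFP-HRAS DMSO replicate 1 (0.0817) or GFP-HRAS rapamycin replicate 2 (0.156). Its median was 0.159 without each of these libraries and 0.545 without GFP-HRAS rapamycin replicate 3. Among lists that did not pass, signs of median and mean differed for neutrophil (-0.25, 0.09), thrombocyte (0.06, -0.22), liver (-0.04, 0.28), amino acid synthesis (0.03, -0.06) and lysosome (0.12, -0.21), and the atrium list had a median of -0.32 and a test pointing up.

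**Figure D3:**
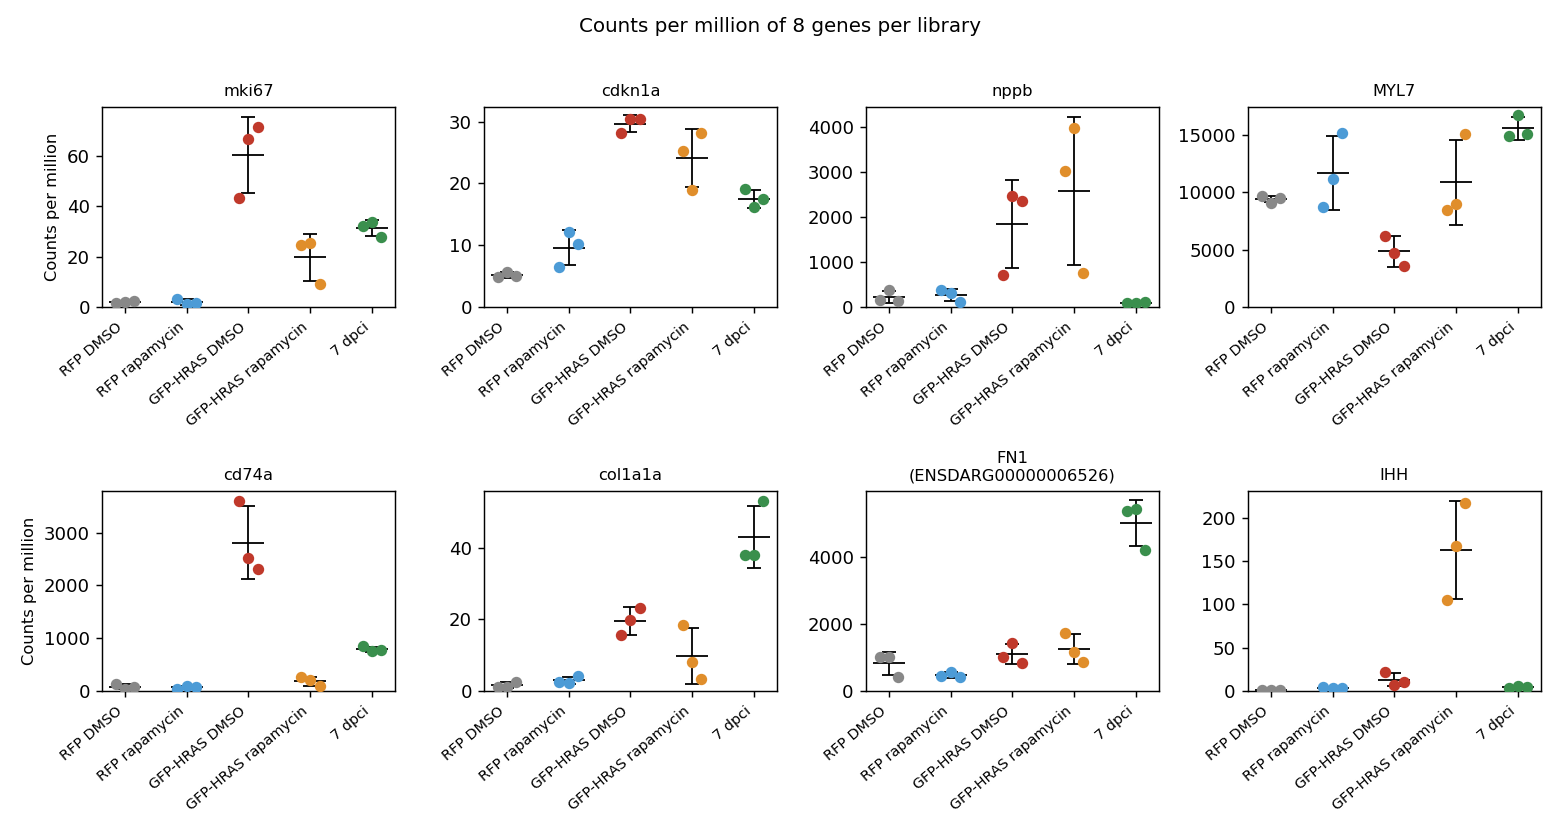
CPM of 8 genes per library (points) with the group mean and SD (bars, n = 3) in the 5 groups. mki67, cdkn1a, nppb and cd74a lie higher in GFP-HRAS DMSO than in RFP DMSO, and IHH is highest in GFP-HRAS rapamycin at 162 ± 56.2 CPM.

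Rapamycin in RFP hearts asks what the inhibitor changed in the RFP line. No gene passed: edgeR called 0 of 16044 genes, with 787 at an unadjusted p under 0.05 (802.2 expected by chance) and a lowest adjusted p of 0.107, while DESeq2 called 27. Without RFP rapamycin replicate 1 the edgeR count was 2. Libraries did not overlap in 11.1% of genes, where chance gives 10%. The cell cycle inhibitor cdkn1a had 0.88 ± 0.237 (edgeR with Benjamini-Hochberg adjusted p = 0.932), the transcription factor KLF4 2.71 ± 0.549 (0.788) and hsp90aa1.1 1.94 ± 0.475 (0.864).

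Shifts over whole lists were measured in the RFP line, with 0 members called in each. Medians lay lower for mitosis (-0.74, or -0.72 with the member at 0 counts set at its bound; adjusted p = 6.59e-06, and adjusted p = 0.712 with an estimated correlation). The same held for S phase (-0.34, 0.0015, and adjusted p = 0.745 with an estimated correlation) and lysosome (-0.18, 0.0369, and adjusted p = 0.623 with an estimated correlation). They lay higher for immediate-early genes (1.56, 9.66e-09, and adjusted p = 0.623 with an estimated correlation), the unfolded protein and heat shock list (0.38, 1.66e-05, and adjusted p = 0.623 with an estimated correlation) and sarcomere (0.31, 8.65e-05, and adjusted p = 0.623 with an estimated correlation). Glycolysis (0.37, 0.000307, and adjusted p = 0.623 with an estimated correlation) and fatty acid oxidation (0.38, 0.000413, and adjusted p = 0.715 with an estimated correlation) had medians above 0. Oxidative phosphorylation (0.16, 0.033, and adjusted p = 0.88 with an estimated correlation; 0.117 with library totals) and neutrophil genes (0.79, 0.0499, and adjusted p = 0.712 with an estimated correlation; 0.0542 with RLE factors) lay higher as well. Adjusted over the list alone, 1 immediate-early gene and 1 heat shock gene were higher and 0 members of the other lists passed. The number of lists past the threshold fell from 10 to 6 without RFP DMSO replicate 2. Mitosis and heat shock passed with each library left out in turn, with medians of -0.475 and -0.388 for mitosis without RFP DMSO replicate 3 and RFP rapamycin replicate 2. For heat shock they were 0.237 and 0.158 without RFP DMSO replicate 2 and RFP rapamycin replicate 1, and the lysosome median was -0.12 without RFP DMSO replicate 3. Immediate-early scores relative to the RFP DMSO mean were 2.27, 1.1 and -0.53 in the 3 RFP rapamycin libraries. Without RFP rapamycin replicate 3 calls were lost for S phase (adjusted p = 0.0534), lysosome (0.0534), sarcomere (0.116, median 0.0813), glycolysis (0.0719, median 0.208), fatty acid oxidation (0.758, median -0.0368) and oxidative phosphorylation (0.959, median -0.0344). Without replicate 1 immediate-early genes (0.0688, median 0.578) and neutrophil genes (0.94, median -0.005) missed, and without replicate 2 lysosome (0.231). Without RFP DMSO replicate 3 oxidative phosphorylation (0.109) and neutrophil genes (0.347, median 0.402) missed. Without RFP DMSO replicate 2 the same held for oxidative phosphorylation (0.504, median 0.0721), fatty acid oxidation (0.0718), glycolysis (0.0676, median 0.249), neutrophil genes (0.156) and lysosome (0.501, median -0.0263).

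The interaction tests whether the rapamycin effect differed between the lines. edgeR called 8 genes, 1 higher and 7 lower, with 2303 at an unadjusted p under 0.05; DESeq2 called 519, and without TMM factors 4 were higher and 121 lower, with a median shift of -0.337. The difference was negative for ciita, the master regulator of class II genes (-3.56 ± 0.512), the chemokine receptor CCR8 (-3.64 ± 0.528), the leukocyte lipid kinase PIK3CD (-3.19 ± 0.464) and UNC93B1, which traffics Toll-like receptors (-2.71 ± 0.344). It was positive for lonrf1 (1.88 ± 0.252), and each of these had an adjusted p of 0.0485. The other 3, named because the count is small, were si:ch211-260p9.3 (-5.10), si:ch211-79k12.1 (-2.89) and ENSDARG00000010729 (-4.83). The count was 81 without RFP DMSO replicate 1, 0 without RFP DMSO replicate 2 or 3 or RFP rapamycin replicate 2 or 3, and 1 without RFP rapamycin replicate 1. In the GFP-HRAS line it was 19 without GFP-HRAS DMSO replicate 1, 0 without replicate 2, 31 without replicate 3 and 0 without GFP-HRAS rapamycin replicate 2.

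Lymphocyte and macrophage lists carried the most negative differences, with 0 members called over all genes. The macrophage list had a median of -1.92 (adjusted p = 2.57e-17, and adjusted p = 0.217 with an estimated correlation; 12 lower adjusted over the list alone). The lymphocyte list had -2.92 (0.000108, and adjusted p = 0.36 with an estimated correlation; 5 lower and 1 higher adjusted over the list alone), and the interferon list had -0.79 (7.16e-05, and adjusted p = 0.671 with an estimated correlation; 6 lower adjusted over the list alone). Matrix genes (-1.12, 9.62e-05), S phase (-0.79, 9.84e-05), mitosis (-0.76, 0.00289; 0.0563 with library totals), smooth muscle (-1.0, 0.0451; 0.225 with library totals) and the unfolded protein list (-0.67, 0.00432) were negative too, each with adjusted p = 0.671 with an estimated correlation and 0 adjusted over the list alone. Positive differences were found for ribosomal proteins (0.63, 6.63e-15), oxidative phosphorylation (0.50, 7.98e-05), mitochondrially encoded genes (0.94, 0.000108), fatty acid oxidation (0.46, 0.0109) and sarcomere (0.40, 0.0109; 2 higher adjusted over the list alone), each with adjusted p = 0.671 with an estimated correlation. Endothelial genes had 0.82 (3.29e-06, and adjusted p = 0.126 with an estimated correlation; 9 higher adjusted over the list alone) and the fetal list 0.57 (0.000695, and adjusted p = 0.126 with an estimated correlation). Calls lost with a library left out were mitosis (0.0853 and median -0.312 without RFP rapamycin replicate 1, 0.169 and -0.364 without GFP-HRAS rapamycin replicate 3) and sarcomere (0.161 and median 0.259 without RFP rapamycin replicate 1, 0.0967 without GFP-HRAS DMSO replicate 3). The unfolded protein list was lost too (0.077 and median -0.433 without RFP rapamycin replicate 1, 0.0915 without GFP-HRAS rapamycin replicate 3). Fatty acid oxidation was lost without RFP DMSO replicate 1 (0.269, median 0.224), RFP rapamycin replicate 1 (0.184, 0.231) or 2 (0.115) and GFP-HRAS rapamycin replicate 3 (0.085, 0.2). Smooth muscle was lost without RFP DMSO replicate 2 (0.0608) or 3 (0.0649), RFP rapamycin replicate 3 (0.48, median -0.501), GFP-HRAS DMSO replicate 2 (0.11, -0.64) or 3 (0.0669), and GFP-HRAS rapamycin replicate 2 (0.0758, -0.66) or 3 (0.169, -0.581). Without GFP-HRAS rapamycin replicate 3 medians were -0.408 for S phase (adjusted p = 0.0138) and -1.32 for interferon genes, and without replicate 1 -1.71 for matrix and -2.11 for smooth muscle. Without RFP DMSO replicate 1 they were 0.314 for oxidative phosphorylation and 0.529 for mitochondrially encoded genes, and without RFP rapamycin replicate 3 1.5 for the latter and 0.974 for fatty acid oxidation. The unfolded protein median was -0.336 without RFP DMSO replicate 2, and the fetal median 0.365 without GFP-HRAS DMSO replicate 1.

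The HRAS effect in rapamycin asks what the oncogene changed under the inhibitor. The proliferation marker mki67 rose by 3.27 ± 0.458 (log2, SE; edgeR with Benjamini-Hochberg adjusted p = 0.00252), cdkn1a by 1.33 ± 0.233 (0.00575) and nppb by 3.29 ± 0.722 (0.0139; 0.0535 without RFP rapamycin replicate 2). The natriuretic peptide gene nppal was at 355 ± 300 CPM against 0.91 (SD, n = 3; 8.57 ± 1.39, adjusted p = 0.0046), and CDK1 was at least 8.2-fold higher. HRAS ENSDARG00000098497 rose by 1.64 ± 0.375 (0.0159), lost without RFP rapamycin replicate 1 (0.0514) or 2 (0.0696) or GFP-HRAS rapamycin replicate 1 (0.0637) or 2 (0.0567), and MYL7 had -0.10 (0.821). Other large rises were SALL1 (ENSDARG00000075891, 8.24 ± 1.21), rln3a (8.18 ± 1.30), hspb9 (7.96 ± 1.33), and, as ratios, jac2 at 388.4 (107.2 to 3213), the retinoid carrier CRABP2 (ENSDARG00000073978) at 295.4 (81.46 to 2445), WNT9B at 192.4 (52.93 to 1594) and MARCKS at 187.8 (51.67 to 1556). The sulfotransferase sult2st1 fell from 69.8 ± 16.1 to 3.69 CPM (-4.24 ± 0.294, adjusted p = 0.000171). SLC45A1 (-5.69 ± 0.683, 0.00153), FAM219A (ENSDARG00000013813, -4.55 ± 0.501, 0.00102), bnip4 (-4.31 ± 0.795) and RAB11FIP4 (ENSDARG00000090170, -3.55 ± 0.462) fell too.

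edgeR called 2909 genes (1672 higher, 1237 lower), and 1960 and 916 without TMM factors, with a median shift of 0.123; libraries did not overlap in 33.1% of genes, where chance gives 10%. The count was 1686 without RFP rapamycin replicate 1, 881 without replicate 2, 1008 without GFP-HRAS rapamycin replicate 1, 989 without replicate 2 and 4864 without replicate 3, the library that stood apart. Of 29 mitosis genes 27 rose, and 28 adjusted over the list alone (median 4.05, or 4.04 with the member at 0 counts at its bound; adjusted p = 1.46e-36, and adjusted p = 0.472 with an estimated correlation). S phase had 16 of 27 higher and 1 lower, and 23 and 1 adjusted over the list alone (median 1.78, adjusted p = 2.84e-10, and adjusted p = 0.494 with an estimated correlation). The matrix list had 14 of 32 higher and 3 lower, and 20 and 3 adjusted over the list alone (median 1.49, adjusted p = 5.31e-05, and adjusted p = 0.725 with an estimated correlation). Examples were COL12A1 at 4.13 ± 0.809 and TIMP2 (ENSDARG00000075261) at 5.93 ± 1.07 higher and the receptor PDGFRA at -2.29 ± 0.366. ERK feedback genes had 8 of 23 higher and 2 lower, and 15 and 2 adjusted over the list alone (median 1.40, adjusted p = 0.00177, and adjusted p = 0.525 with an estimated correlation). Among them were the ERK inhibitor SPRED2 at 1.19 ± 0.196 and the cytokine il11b at 5.54 ± 1.06. The unfolded protein list had 7 of 23 higher, and 11 adjusted over the list alone (median 0.85, adjusted p = 0.00332, and adjusted p = 0.725 with an estimated correlation). Erythrocyte genes had 6 of 9 lower, and 7 adjusted over the list alone (median -1.51, adjusted p = 7.26e-05, and adjusted p = 0.472 with an estimated correlation). The fetal list had 9 of 21 higher and 1 lower, and 11 and 2 adjusted over the list alone (median 0.61, adjusted p = 0.0242, 0.074 without RFP rapamycin replicate 1, and adjusted p = 0.472 with an estimated correlation). The macrophage list had 4 of 23 higher, and 6 adjusted over the list alone (median 0.89, adjusted p = 0.0199, 0.352 and a median of 0.34 without GFP-HRAS rapamycin replicate 1, and adjusted p = 0.897 with an estimated correlation). Immediate-early genes had 1 of 19 higher, and 0 adjusted over the list alone (median 0.85, adjusted p = 0.0199, 0.299 without RFP rapamycin replicate 3, 0.115 without GFP-HRAS rapamycin replicate 2, and adjusted p = 0.897 with an estimated correlation). Their median was 0.512 and 0.346 without these libraries and 1.61 without RFP rapamycin replicate 1, and the fetal median 0.947 without GFP-HRAS rapamycin replicate 3.

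The HRAS effects in DMSO and in rapamycin share no library. Across 16044 genes, which are not independent replicates, their log2 fold changes had Pearson r = 0.794 and Spearman rho = 0.783. In both media 1452 genes were called higher (415.9 expected of independent lists) and 1036 lower (279.9 expected), and 6 went opposite ways. Of the genes called in rapamycin, 60.8% had a smaller change there than in DMSO.

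Injured hearts were compared with RFP hearts in comparisons added after seeing the data. Table, strain, 4-OHT and vehicle or rapamycin differed along with the injury. Matrix genes were higher at 7 dpci. Against RFP DMSO, COL12A1 was at 230 ± 29.8 CPM against 0.936 (SD, n = 3; log2 fold change 7.94 ± 0.856, edgeR with Benjamini-Hochberg adjusted p = 0.000127). The collagen col1a1a was at 43.0 ± 8.78 against 1.69 (4.66 ± 0.554) and FN1 ENSDARG00000006526 at 5015 ± 688 against 827 ± 349 (2.60 ± 0.35). The clotting factor subunit F13A1 (ENSDARG00000045453) was at 131.5 ± 48.8 CPM against 0.153 (9.63 ± 1.16, adjusted p = 2e-04). The proliferation marker mki67 was at 31.3 ± 3.1 CPM against 2.01 (3.95 ± 0.429), with PCNA at 1.23 ± 0.228 and cdkn1a at 1.75 ± 0.219. The heart hormone gene nppa was lower (-1.32 ± 0.303, adjusted p = 0.00507), and nppb had -1.19 (0.147). Other large differences were LUM (7.04 ± 0.903), CILP2 (8.13 ± 1.07), the ratios of mhc2dab at 931.4 (257.5 to 7696), spp1 at 451.5 (80.68 to 17870) and cd248b at 334.1 (59.61 to 13230). Lower were CYP24A1 (-7.79 ± 1.30), SLC45A1 (-5.51 ± 0.733), KLF9 (-5.09 ± 1.24) and TWF2 (ENSDARG00000009727, -4.82 ± 0.638). MARCKS was at least 154.5-fold higher.

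edgeR called 5984 of 16421 genes against RFP DMSO (3079 higher, 2905 lower; 3517 and 2127 without TMM factors, median shift 0.145) and 5665 against RFP rapamycin (2818 and 2847; 3711 and 1650 without TMM factors, median shift 0.228). Libraries did not overlap in 57.7% and 52.5% of genes, where chance gives 10%. Against RFP DMSO, 26 of 33 matrix genes were higher and 1 lower, and 29 and 1 adjusted over the list alone (median 3.42, adjusted p = 1.85e-19, and adjusted p = 0.286 with an estimated correlation). Examples were SPARC at 4.64 ± 0.433 and COL6A3 at 4.94 ± 0.521. Mitosis had 26 of 29 higher, and 26 adjusted over the list alone (median 3.25, adjusted p = 5.75e-23, and adjusted p = 0.286 with an estimated correlation). S phase had 23 of 27 higher, and 24 higher and 2 lower adjusted over the list alone (median 1.72, adjusted p = 5.39e-11, and adjusted p = 0.39 with an estimated correlation). The macrophage list had 17 of 24 higher, and 18 adjusted over the list alone (median 2.26, adjusted p = 7.05e-10, and adjusted p = 0.39 with an estimated correlation). The epicardial list had 9 of 13 higher and 1 lower, and the same adjusted over the list alone (median 1.68, adjusted p = 0.000326, and adjusted p = 0.286 with an estimated correlation). Examples were hapln1a at 4.82 ± 0.715 and TCF21 at 1.86 ± 0.30. Smooth muscle had 10 of 12 higher, and 10 adjusted over the list alone (median 1.95, or 2.07 with the member at 0 counts at its bound; adjusted p = 0.00139, and adjusted p = 0.481 with an estimated correlation). The unfolded protein list had 10 of 23 higher and 1 lower, and the same adjusted over the list alone (median 0.73, adjusted p = 0.00509, and adjusted p = 0.536 with an estimated correlation). Erythrocyte genes had 5 of 9 higher and 1 lower, and 6 and 1 adjusted over the list alone (median 0.95, adjusted p = 0.0139, 0.0764 without RFP DMSO replicate 1, and adjusted p = 0.536 with an estimated correlation). The erythrocyte median was 1.47 without RFP DMSO replicate 3. Oxidative phosphorylation had 8 of 29 higher and 1 lower, and 8 and 0 adjusted over the list alone (median 0.41, adjusted p = 0.0344, and adjusted p = 0.798 with an estimated correlation). It was lost without RFP DMSO replicate 2 (0.094, median 0.27) or 3 (0.0526) or 7 dpci replicate 2 (0.0647). Ribosome biogenesis had 23 of 28 lower, and 24 adjusted over the list alone (median -1.22, adjusted p = 1.23e-11, and adjusted p = 0.39 with an estimated correlation). Among them were BYSL at -1.88 ± 0.229 and DDX21 at -2.42 ± 0.349. Ribosomal proteins had 42 of 48 lower, and 46 adjusted over the list alone (median -0.60, adjusted p = 2.42e-10, and adjusted p = 0.536 with an estimated correlation).

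Against RFP rapamycin, THBS4 (ENSDARG00000020072) was at least 280.2-fold higher, spp1 at least 141.5-fold and the collagenase mmp13b at least 78.2-fold, and F13A1 (ENSDARG00000045453) had a ratio of 2078 (710.9 to 10080). Matrix genes had 28 of 33 higher, and 28 adjusted over the list alone (median 2.97, adjusted p = 2.73e-19, and adjusted p = 0.166 with an estimated correlation). Mitosis had 27 of 29 higher, and 27 adjusted over the list alone (median 4.17, or 3.95 with the member at 0 counts at its bound; adjusted p = 8.48e-30, and adjusted p = 0.166 with an estimated correlation). S phase had 24 higher and 1 lower, and the same adjusted over the list alone (median 2.16, adjusted p = 7.03e-15, and adjusted p = 0.246 with an estimated correlation). In the macrophage list 19 were higher, and 21 adjusted over the list alone (2.37, adjusted p = 1.89e-11, and adjusted p = 0.271 with an estimated correlation), and in the epicardial list 9 were higher and 1 lower, and the same adjusted over the list alone (1.46, adjusted p = 0.000151, and adjusted p = 0.166 with an estimated correlation). Thrombocyte (median 1.06, 6 of 10 higher, 6 adjusted over the list alone, adjusted p = 0.00685, and adjusted p = 0.166 with an estimated correlation) and smooth muscle genes (1.5, 6 higher, 6 adjusted over the list alone, adjusted p = 0.00685, and adjusted p = 0.558 with an estimated correlation) passed. Erythrocyte genes had 5 higher and 1 lower, and 6 and 1 adjusted over the list alone (1.01, adjusted p = 0.0244, 0.109 without RFP rapamycin replicate 3, and adjusted p = 0.558 with an estimated correlation). Ribosome biogenesis had 21 lower, and 21 lower and 1 higher adjusted over the list alone (median -1.05, adjusted p = 1.67e-10, and adjusted p = 0.509 with an estimated correlation). Ribosomal proteins had 39 lower, and 45 adjusted over the list alone (-0.65, adjusted p = 6.12e-11, and adjusted p = 0.558 with an estimated correlation).

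Injured and GFP-HRAS DMSO hearts were set against each other to ask where they differed. MYL7 was higher at 7 dpci, at 15570 ± 1000 CPM against 4841 ± 1320 (SD, n = 3; log2 fold change 1.69 ± 0.267, edgeR with Benjamini-Hochberg adjusted p = 0.00104), and the globin hbaa1 differed by 3.98 ± 0.362 (0.000115). The natriuretic peptide gene nppb was lower, at 99.5 ± 15.2 CPM against 1845 ± 979 (-4.21 ± 0.697, adjusted p = 0.00132), as were nppa (-1.72 ± 0.306), DUSP6 at 2.02 CPM against 29.3 (-3.86 ± 0.776, adjusted p = 0.00357) and ASNS (-0.92 ± 0.187). F13A1 (ENSDARG00000045453) was higher (8.27 ± 1.03), with GPNMB (4.90 ± 0.68), sult2st1 (4.70 ± 0.317) and FN1 ENSDARG00000006526 (2.18 ± 0.344). MYH11 (ENSDARG00000100972) was lower at a ratio of 898.7 (161.0 to 35530), NPAS4 at least 108.0-fold, jac7 by a log2 change of -7.67, prf1.8 of -6.74 and nppal of -6.27. For mki67 the difference was -0.95 ± 0.368 (adjusted p = 0.0684).

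edgeR called 4733 genes (2192 higher and 2541 lower at 7 dpci; 1290 and 4617 without TMM factors, median shift -0.393), and libraries did not overlap in 53.5% of genes, where chance gives 10%. The count was 2996 without GFP-HRAS DMSO replicate 2 and 2948, 3124 and 2965 without 7 dpci replicates 1, 2 and 3. Higher lists were erythrocyte (9 of 9 higher, 9 adjusted over the list alone; median 3.23, adjusted p = 1.93e-12, and adjusted p = 0.133 with an estimated correlation) and oxidative phosphorylation (24 of 29, 24 higher and 1 lower adjusted over the list alone; 0.998, 2.09e-13, and adjusted p = 0.215 with an estimated correlation). So were fatty acid oxidation and TCA cycle (18 of 29 higher and 1 lower, 20 and 1 adjusted over the list alone; 1.13, 1.77e-08, and adjusted p = 0.34 with an estimated correlation) and sarcomere (16 of 28 higher and 1 lower, the same adjusted over the list alone; 0.86, 5.22e-07, and adjusted p = 0.215 with an estimated correlation). The mitochondrial enzyme MDH2 had 1.57 ± 0.283, UQCRC2 1.24 ± 0.164 and actc1a 1.42 ± 0.143. Matrix (11 of 33 higher and 2 lower, 14 and 2 adjusted over the list alone; 1.08, 0.000677, and adjusted p = 0.509 with an estimated correlation) and epicardium (7 of 13 higher, 8 higher and 1 lower adjusted over the list alone; 1.30, 5.72e-05, and adjusted p = 0.133 with an estimated correlation) were higher. Endothelium (11 of 23 higher, 13 higher and 1 lower adjusted over the list alone; 0.56, 5.72e-05, and adjusted p = 0.144 with an estimated correlation) was higher as well, with TCF21 at 2.39 ± 0.304, NFATC1 at 2.1 ± 0.213 and vwf at 2.61 ± 0.249. Mitochondrially encoded genes (5 of 13 higher, 10 adjusted over the list alone; 0.88, 0.000882, and adjusted p = 0.509 with an estimated correlation) were higher, and so were thrombocyte (5 of 10 higher and 1 lower, 5 and 2 adjusted over the list alone; 0.76, 0.0151, and adjusted p = 0.21 with an estimated correlation) and skeletal muscle (2 of 4, 2 adjusted over the list alone; 2.41, 0.00657, and adjusted p = 0.133 with an estimated correlation) genes. The thrombocyte median was 1.15 without GFP-HRAS DMSO replicate 1, and the skeletal muscle median 3.69 without 7 dpci replicate 3.

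Lower at 7 dpci than in GFP-HRAS DMSO was the interferon list (15 of 20 lower, 16 adjusted over the list alone; median -1.82, adjusted p = 4.26e-07, and adjusted p = 0.269 with an estimated correlation). Members included ifit8 at -4.98 ± 0.647 and mxb at -4.50 ± 0.542. Ribosome biogenesis was lower (19 of 28, 24 adjusted over the list alone; -1.14, 4.06e-10, and adjusted p = 0.34 with an estimated correlation). Mitosis (21 of 29, 24 adjusted over the list alone; -1.47, 7.81e-09, and adjusted p = 0.426 with an estimated correlation) was lower, with UBE2C at -2.08 ± 0.327 and CCNB1 at -2.12. The macrophage list had 7 of 24 lower, and 8 adjusted over the list alone (-0.73, 0.0117, and adjusted p = 0.59 with an estimated correlation). The macrophage median was -0.375 without GFP-HRAS DMSO replicate 1 (adjusted p = 0.045), and that of the ERK feedback list -0.634 without 7 dpci replicate 1. Amino acid synthesis (9 of 20, 9 adjusted over the list alone; -0.61, 0.00764, and adjusted p = 0.426 with an estimated correlation) was lower, as were ERK feedback genes (4 of 23, 3 adjusted over the list alone; -1.03, 0.0151, and adjusted p = 0.456 with an estimated correlation), with SPRED2 at -1.38 ± 0.185. The lymphocyte list (5 of 12, 5 adjusted over the list alone; -1.65, 0.0199, 0.0854 without GFP-HRAS DMSO replicate 1, 0.0829 with library totals, and adjusted p = 0.459 with an estimated correlation) was lower. S phase had 0 called over all genes and 0 adjusted over the list alone (-0.64, 0.0151, 0.0669 without GFP-HRAS DMSO replicate 3, 0.0661 without 7 dpci replicate 3, and adjusted p = 0.59 with an estimated correlation).

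The overlap between the injured hearts and the HRAS effect was measured with comparisons that share no library. Of 16044 genes, 1894 were higher in 7 dpci than in RFP rapamycin and higher with HRAS in DMSO (664.2 expected of independent lists), and 1730 were lower in both (644.1 expected; Fisher's exact p at most 1e-300 for each). Another 42 and 61 went opposite ways (604.1 and 708.2 expected). Across genes the log2 fold changes had Pearson r = 0.706 and Spearman rho = 0.672, and 75.0% had the same sign. With 7 dpci against RFP DMSO and HRAS in rapamycin, 955 genes were higher in both (304.9 expected) and 706 lower in both (224.0 expected, Fisher's exact p = 1.79e-229), with 21 and 21 opposite, r = 0.642 and rho = 0.597. That shared count of 1661 was 889 without RFP rapamycin replicate 1, 594 without replicate 2, 619 without GFP-HRAS rapamycin replicate 1, 653 without replicate 2 and 2410 without replicate 3. Both effects are differences from the RFP line and its treatment, so part of the overlap can come from what sets that line apart.

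The sets of genes that differed at 7 dpci were then followed in the rapamycin comparison. The 2670 genes higher in 7 dpci than in RFP rapamycin had a median log2 fold change of 1.67 with HRAS in DMSO (camera p = 2.48e-50, and p = 0.00764 with an estimated correlation). They had -0.66 with rapamycin in GFP-HRAS (p = 1.26e-25, and p = 0.0307 with an estimated correlation), where 34 were called higher and 558 lower. The 2847 lower genes had -0.82 with HRAS (p = 2.03e-33, and p = 0.035 with an estimated correlation). Their median was 0.34 with rapamycin (p = 1.36e-14, and p = 0.142 with an estimated correlation), where 413 were called higher and 19 lower. Sets from 7 dpci against RFP DMSO, of 2926 higher and 2905 lower genes, had medians of 0.88 (p = 1.3e-34) and -0.50 (p = 3.87e-27) with HRAS in rapamycin (p = 0.0209 and 0.0635 with an estimated correlation). The same sets had -0.46 (p = 2.18e-14) and 0.26 (p = 8.01e-10) with rapamycin in GFP-HRAS (p = 0.0873 and 0.255 with an estimated correlation).

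**Figure D4:**
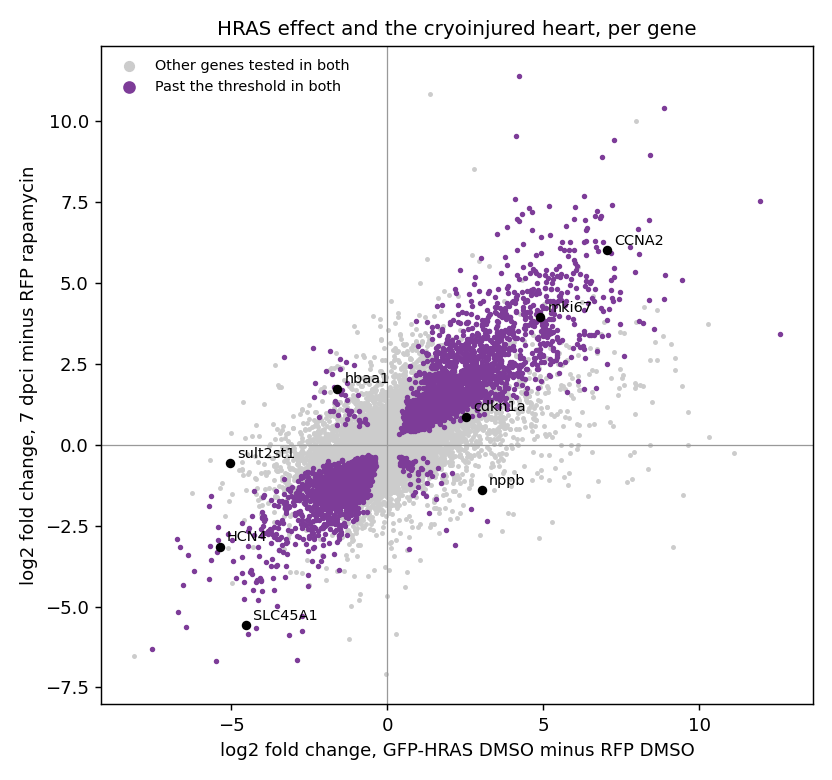
Log2 fold change of each gene with HRAS in DMSO (x axis) against 7 dpci minus RFP rapamycin (y axis), with genes past the threshold in both in purple. Across 16044 genes Pearson r is 0.706, with 1894 genes higher and 1730 lower in both.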

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

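Of the tests in this part, the counts over other splits of the libraries were fixed before their results were seen, and the tests of replicate 3, of mhc2dab and of the cell type lists were chosen only after the results were seen.

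The difference between the rapamycin effects in the GFP-HRAS and RFP lines stood out by its own test for 8 genes and 15 lists. The log2 difference was -2.71 for UNC93B1, 1.88 for lonrf1, -3.56 for ciita, -3.64 for CCR8, -3.19 for PIK3CD, -5.10 for si:ch211-260p9.3, -2.89 for si:ch211-79k12.1 and -4.83 for ENSDARG00000010729. ciita, CCR8, PIK3CD and UNC93B1 are genes of immune cells. Median differences of the lists were -0.789 for S phase, -0.76 for mitosis, 0.396 for sarcomere, 0.571 for fetal and border-zone genes, 0.504 for oxidative phosphorylation, 0.941 for mitochondrially encoded genes, 0.461 for fatty acid oxidation and TCA cycle, -1.12 for matrix, -1.92 for macrophage, -2.92 for lymphocyte, 0.819 for endothelium, -1 for smooth muscle, 0.627 for ribosomal proteins, -0.788 for interferon response and -0.669 for the unfolded protein list. None of the 15 lists passed with an estimated correlation. Of 100 splits of the libraries, 5 gave 8 or more genes, the real split included, but this share does not measure chance. The 8 others that regrouped only RFP libraries kept the rapamycin effect in GFP-HRAS. Of these, 4 gave 15 to 773 genes and 4 gave 0. The other 91 moved that effect into the spread and gave at most 1 each, so chance was not excluded.

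For the pairwise comparisons, 10 splits are too few for a share under 0.05. The real split gave the highest count, 1 of 10 splits, for the HRAS effect in DMSO (7621, highest other 0), rapamycin in GFP-HRAS (1947, highest other 0), the HRAS effect in rapamycin (2909, highest other 2), and 7 dpci against RFP DMSO (5984), RFP rapamycin (5665) and GFP-HRAS DMSO (4733), each with 0 as the highest other. For rapamycin in RFP the real count was 0 and the highest other 1, and all 10 splits gave at least 0.

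GFP-HRAS rapamycin replicate 3 lay at -11.9 on the first principal component, between the RFP libraries and its own group at 44.5 and 32.8. A wrong label on an RFP library was argued against by the mitosis list, with a score of 1.85 against -0.861 to 0.3 in the 6 RFP libraries, 1.55 above the highest, where their range was 1.16; of the 13 lists that passed with HRAS in DMSO, 5 lay beyond the RFP libraries in the direction of HRAS, 2 of them by more than their range, and 8 did not. Shares of genes above all 6 RFP libraries did not decide it alone. They were 50% of 12 genes near 0 in the RFP lines and 45% of the 3991 genes higher with HRAS in DMSO. Replicates 1 and 2 had 80.7% and 74.2% of the latter. Each RFP library was set against only the other 5, an easier bound, and had 8.17% to 27.5%. A share of 14.3% is expected of a 7th RFP library. Another time of collection as the whole cause was argued against, since its deviation and that of RFP rapamycin replicate 3, which shared its low clock score, had a correlation of -0.0752 across other genes. A mixture with RFP RNA was not decided, as 0.972% of genes lay over 2-fold outside the range of the other rapamycin libraries, where those had 0.256% to 2.14%, and a weaker response to HRAS or a stronger one to rapamycin in that library may account for it and was not tested.

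The class II gene mhc2dab had 0 to 2 counts in 5 of the 6 RFP libraries and 5811 to 7796 in GFP-HRAS DMSO. More cells that carry class II molecules, as the only cause, was argued against: the median ratio of mhc2dab to its partner chain mhc2daa in RFP libraries was 0.0222 of that in GFP-HRAS DMSO. A haplotype that only some fish carry is a candidate explanation, since 1 of the 6 RFP libraries, RFP rapamycin replicate 2, had a ratio of 0.584 with 177 counts, near the 0.705 to 0.791 of GFP-HRAS DMSO, while the others had 0 to 0.0667. HRAS as a requirement for mhc2dab was argued against, since 4 of the 9 libraries without GFP-HRAS reached at least 50% of the lowest ratio in GFP-HRAS DMSO, the 3 at 7 dpci with 0.412 to 0.568 on 359 to 1063 counts; GFP-HRAS rapamycin had 0.508 to 0.735. An effect of HRAS on mhc2dab within the transgenic lines and reads shared with other class II genes stay open and were not tested.

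With HRAS in DMSO, respiratory, ribosomal protein and some cardiomyocyte genes lay lower and macrophage and lymphocyte lists higher; each list call was lost with an estimated correlation. A lower share of cardiomyocyte RNA, alone, would raise markers of the other cell types alike, and it was argued against by the endothelial median of -1.34 beside 3.06 for macrophage genes. The fall of the macrophage list with rapamycin did not rest on replicate 3 alone, since its median was -1.9 without that library, at an adjusted p of 4.91e-17 with the preset correlation; with an estimated correlation the list missed in all libraries together (adjusted p = 0.168). More of these leukocytes in GFP-HRAS hearts and fewer with rapamycin, or a change within these cells, may account for the pattern, and cell numbers were not measured.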

How the results depend on the processing

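The fit of 7 dpci against other groups and its alternatives were chosen only after the data were seen, and the other alternatives were planned. The alternatives of the comparisons that need uninjured hearts were not run. Over alternatives and left-out libraries, 7554 values of named genes kept their side of the threshold, 522 fell below it and 109 rose past it. For lists these were 2950, 170 and 98. Among values called in at least 1 of the settings compared, gene directions reversed in 0, and 6 list medians reversed, each for rapamycin in RFP. Without RFP rapamycin replicate 3 medians were -0.0344 for oxidative phosphorylation (up to 0.23 without RFP DMSO replicate 1), -0.0368 for fatty acid oxidation (up to 0.537 without RFP rapamycin replicate 2) and 0.174 for ribosome biogenesis (down to -0.256 without RFP rapamycin replicate 1). Without RFP rapamycin replicate 1 they were -0.005 for neutrophil genes (up to 1.18 without RFP rapamycin replicate 3) and -0.377 for amino acid synthesis (up to 0.127 without RFP rapamycin replicate 3), and without RFP DMSO replicate 3 the erythrocyte median was 0.46 (down to -0.228 without RFP DMSO replicate 1). The glycolysis median for rapamycin in GFP-HRAS turned to -0.128 with library totals while its test kept its direction, and 218 medians of lists that passed under neither setting changed sign, the sarcomere median for HRAS in DMSO among them. The cause was not tested for the changes given here. With an estimated correlation, 0 lists passed in each of the 8 comparisons, and 4 of the sets that differed at 7 dpci missed the threshold: -0.5 (p = 0.0635), 0.337 (0.142), -0.465 (0.0873) and 0.263 (0.255). Rapamycin in GFP-HRAS gave 3472 genes with library totals, 3126 in DESeq2 and 766 in a fit of the 6 libraries alone; the interaction gave 125 with library totals, 26 without the filter and 519 in DESeq2. Rapamycin in RFP gave 27 in DESeq2, and the HRAS effect in rapamycin 838 in a fit of its 6 libraries. Calls shared by 7 dpci against RFP rapamycin and the HRAS effect in DMSO numbered 2363 with a 2-fold threshold.

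With 1 library left out, the count ranged from 533 to 2305 for rapamycin in GFP-HRAS, 0 to 2 for rapamycin in RFP (6 to 13 lists), 881 to 4864 for the HRAS effect in rapamycin, 0 to 81 for the interaction, 2948 to 4296 for 7 dpci against GFP-HRAS DMSO, and 594 to 2410 for calls shared by 7 dpci against RFP DMSO and HRAS in rapamycin. The HRAS effect in DMSO ranged from 5793 to 7312. Where a group kept 2 libraries, the spread came from all groups of the fit.

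With the replicate number as a block, rapamycin in GFP-HRAS gave 1271 genes and the interaction 44, and the other counts stayed within 1.5 times. The numbers do not pair the libraries: deviations of same-numbered libraries had correlations from -0.34 to 0.0529.

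Genes with few counts were imprecise, as wide counting intervals show. In simulated counts with few changed genes, 4.48% to 11.9% of 2-fold changes were recovered in pairwise comparisons. Recovery in fits with many calls was not measured, and uncalled genes can hold such changes.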

Other observations

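All genes here were chosen after their values were seen, and no test beyond the fits above was run on them. A gene with human-style symbol MYH6 (ENSDARG00000079564), not shown to be atrial, was at 4800 ± 1580 CPM in GFP-HRAS DMSO and 3640 ± 1780 in GFP-HRAS rapamycin against 393 ± 110 in RFP DMSO, 485 ± 39 in RFP rapamycin and 1970 ± 129 at 7 dpci (SD, n = 3). Atrium list member myh6 (ENSDARG00000090637) was at 314 ± 172, 230 ± 115, 240 ± 146, 216 ± 40.1 and 190 ± 77.3 CPM in the same groups. That list scored -1.06 ± 0.407 in GFP-HRAS DMSO and -1.13 ± 0.388 in GFP-HRAS rapamycin relative to the RFP DMSO mean.

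The class II transactivator ciita was at 27.7 ± 8.94 CPM in GFP-HRAS DMSO, 7.66 ± 1.22 at 7 dpci, 2.05 ± 0.488 in GFP-HRAS rapamycin, 1.58 ± 0.552 in RFP DMSO and 1.39 ± 0.494 in RFP rapamycin, and the class II gene mhc2daa at 387 ± 57.2, 70.2 ± 21.1, 22 ± 15.8, 3.31 ± 0.541 and 6.69 ± 8.89 CPM in the same groups.

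A score of clock genes was -0.95 in GFP-HRAS rapamycin replicate 3 and -0.16 in RFP rapamycin replicate 3, and 1.15 to 3.18 in the other libraries.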
